A study of Homo sapiens with 6 samples.

How the data were processed

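RNA was sequenced from H1 human embryonic stem cells in 6 samples: 2 wild type, 2 hemizygous and 2 homozygous for DICER1 S1344L. The RNA was total RNA and the libraries came from an unstranded Illumina TruSeq RNA kit, per the labels' protocols. The authors trimmed reads with cutadapt and aligned them with HISAT2 to hg38, per the submitters' processing notes, which state no versions. The program that counted reads and the annotation it used are not given in the sources used here. The deposited table holds raw counts per gene, whole numbers with no normalization. Every gene in it has more than 0.5 CPM (counts scaled to a common library size) in at least 3 samples, so genes with low counts were left out before deposit, and genes silent in most samples are not analysed here. Genes that overlap on opposite strands cannot be told apart in unstranded libraries.

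The table has 16199 genes, of which 1243 are named by an Ensembl ID. For positions, gene types and 3' UTRs, 15915 genes were matched to GENCODE release 29 (GRCh38), by current symbol (14866), by ID (985) or by the symbol of that release (64), and 284 were not matched. The listed totals were 38164848 to 52924532 counts per sample. Counts come from reads without molecular identifiers, so counting precision is a lower limit on the error. The samples were grouped by genotype as their titles give it. The labels do not say whether the 2 samples of a genotype are separate cultures or clones, so p-values measure the spread between these samples, which may be technical.

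The 3 comparisons, hemizygous and homozygous against wild type and homozygous against hemizygous, used edgeR 4.0.16 in R 4.3.3 on all 6 samples: TMM normalization, filterByExpr by group (which removed 0 genes), the quasi-likelihood test, and Benjamini-Hochberg adjusted p under 0.05. The fit left 3 residual degrees of freedom. Replicate numbers come from the sample titles, and the labels do not say what they mark. After each genotype's mean was removed, samples with the same number deviated together across genes (correlations of deviations 0.741 for wild type and hemizygous, 0.357 for wild type and homozygous, 0.476 for hemizygous and homozygous). The numbers were therefore treated as a pairing and a fit with the replicate number as a block was run beside the test, with 2 residual degrees of freedom. With only 2 numbers this pairing rests on little. Libraries were checked for copies of each other, and chi-square per degree of freedom between libraries was 11.5 to 97.4.

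Gene lists, 36 in all, were tested with camera of limma 3.58.1 (preset inter-gene correlation 0.01, two-sided, adjusted over lists within a comparison), beside camera with an estimated correlation and fry. Members were counted over all genes and when adjusted over the list alone. The lists covered core and naive pluripotency, markers of neural ectoderm, neurons, neural crest, primitive streak, definitive endoderm, mesoderm, trophoblast and amnion, and fibroblast and mesenchyme, and also miRNA processing and host transcripts, p53, cell death, interferon, cell cycle, signalling, junction, mesenchymal, metabolic, stress, immediate early, imprinted, 20q11.21, mitochondrial, histone and ribosomal genes, and literature targets of 5 microRNA groups. Of the listed genes those absent from the table were left out.

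For 56 seed families, named here by 1 or 2 of their members, genes with a match to seed positions 2 to 8 in their longest annotated 3' UTR of at least 30 nt were compared with the other genes with such a UTR (13197 in all). Signed z values of the edgeR test were corrected for 3' UTR length, 3' UTR GC and mean expression by natural splines with 3 degrees of freedom each and tested with cameraPR (preset correlation 0.01). The effect given is the mean residual log2 fold change of genes with sites minus that of genes without. The mean effects of 22 families of the 5p arm and 17 of the 3p arm were compared by a two-sided permutation test with 1e+05 resamples, with families as units. All 7-mers found in at least 50 genes, 16263 of 16384, were ranked by the same residuals. Sequences were handled with Biostrings 2.70.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the annotation and drew the figures.

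The genes to name were DICER1, DROSHA, DGCR8, XPO5, AGO2, POU5F1, SOX2, NANOG and LIN28A in each comparison. To these were added, among genes past the edgeR threshold with a symbol, a mean CPM of at least 1 in a group and no overlap between the replicates of both groups, the 8 with the largest rise and the 8 with the largest fall (6 for homozygous against hemizygous), and up to 2 rising and 2 falling members of each list. As edgeR called no genes, this rule named only the 9 fixed genes. The genes called by DESeq2 1.42.0, and those the same rule takes from DESeq2 with the replicate number as a block, were named after their values were seen. The tests, lists, seed families, naming rule and main alternatives were chosen before the data were examined.

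Alternatives were DESeq2, limma-voom, RLE and upper-quartile factors, a CPM filter (at least 1 CPM in 2 samples), no filter, an adjusted p under 0.01, a log2 fold limit of 1, the 2 compared groups alone, the replicate block and leaving out each sample in turn. For seed sites they were also 8mer sites, the shortest 3' UTR, no covariates and fewer families. DESeq2 with the replicate block, and for seed sites limma-voom, the 2 groups alone, upper-quartile factors and the CPM filter, were added after the data were seen, as were the alternatives for 7-mer ranks. Where a sample was left out, its group had 1 sample, whose spread was assumed to be that of the other groups. To weigh gene length and GC, log2 fold changes were corrected for trends on transcript length, transcript GC and mean expression. Fold changes along chromosomes were summarised in windows of 25 genes.

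The methods were tested on simulated counts with 2 datasets and 200 changed genes in each, over 16199 genes. Counts were drawn from the real means, library sizes and replicate-number differences, with the spread of the blocked fit. Every genotype was given the same replicate difference, whereas deviations in the data correlated at 0.741, 0.357 and 0.476. This setting favours the fits with the block, so their gain in recovery is partly built in. Shared calls were simulated in 50 further datasets without changed genes. In hemizygous against wild type edgeR recovered 9% of genes changed 2-fold and 70.5% of those changed 4-fold, with 0.625% false calls, and limma-voom 8% and 70.5%. DESeq2 recovered 56.5% and 90.5% with 1.01% false calls. With the replicate block edgeR recovered 80.5% and 99.5% with 10.9% false calls, and DESeq2 74% and 94% with 10.9% false calls. In homozygous against wild type the corresponding shares were 9.5% and 66.5% for edgeR with 0% false calls, 7% and 66.5% for limma-voom, and 58.5% and 88.5% for DESeq2 with 0.676% false calls. With the block they were 80.5% and 98% for edgeR with 11.9% false calls, and 76.5% and 92.5% for DESeq2 with 9.38% false calls. Camera called a list with every member raised 2-fold (adjusted p = 6.94e-165) and 0 of 30 random lists. Genes were drawn independently of each other, so this check could not show false calls from list members that vary together. It also did not try smaller shifts. For seed sites a shift of -0.3 SD in 2474 genes of miR-30-5p (-0.0715 and -0.0937 on the log2 scale in hemizygous and homozygous against wild type) was not called, a shift of -0.6 SD (-0.143 and -0.187) was called, and 0 of the 55 other families were called.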

Results

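RNA was sequenced from H1 cells, a human embryonic stem cell line, in 3 genotypes with 2 samples each: the unedited parent (wild type), cells hemizygous for the S1344L change in DICER1, and cells homozygous for it. DICER1 is the enzyme that releases mature microRNAs from their hairpin precursors. The listed counts summed to 52924532 and 38164848 in wild type 1 and 2, 39693194 and 51598026 in hemizygous 1 and 2, and 46152759 and 39565897 in homozygous 1 and 2, over 16199 genes. Expression is given in CPM (counts scaled to a common library size), as mean ± SD of 2 samples unless another error is named, and differences as log2 fold changes. The spread between samples, and not counting error, limited most comparisons at this depth.

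Wild-type and hemizygous samples separated by replicate number and not by genotype on the first principal component. This component held 59.1% of the variance and placed wild type 1 at -34.5 and hemizygous 1 at -39.8, against 20.6 and 22.03 for wild type 2 and hemizygous 2, with homozygous 1 at 3.15 and homozygous 2 at 28.5. The second component, with 15.1%, set homozygous 1 apart at 27.8. Wild type 1 and 2 differed more than 2-fold in 824 genes, hemizygous 1 and 2 in 933 and homozygous 1 and 2 in 318. Ribosomal protein genes took 5.19% and 6.02% of the counts in wild type 1 and 2, 4.51% and 6.43% in hemizygous 1 and 2, and 5.82% and 6.76% in homozygous 1 and 2.

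**Figure D1:**
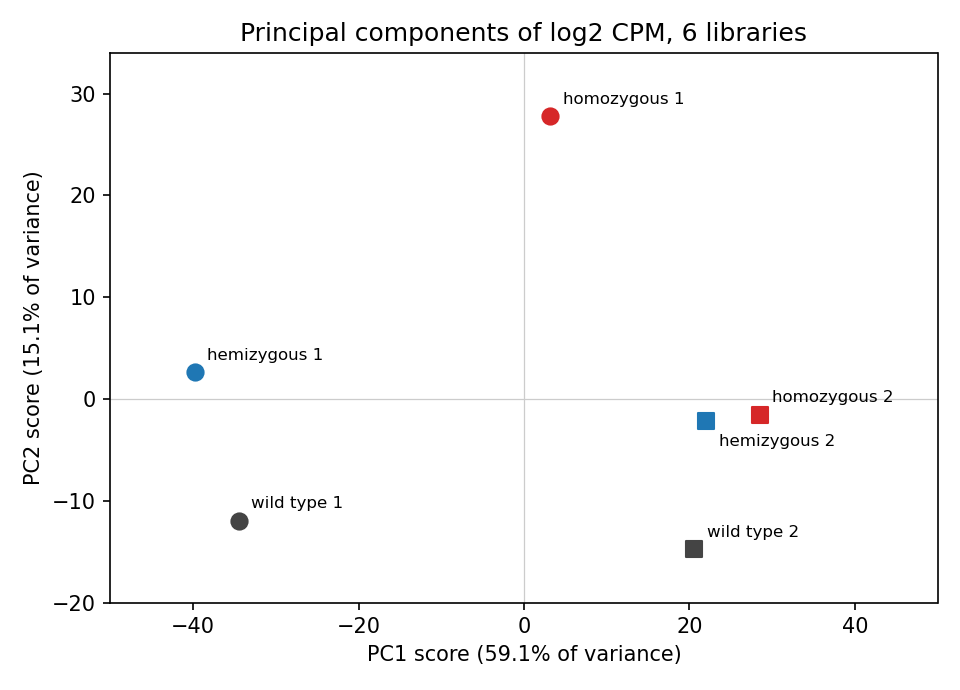
Scores of the 6 samples on the first and second principal components of log2 CPM, with the percent of variance on each axis. Wild type 1 and hemizygous 1 lie at -34.5 and -39.8 on the first component, and homozygous 1 lies apart at 27.8 on the second.

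The microRNA machinery and the core pluripotency factors, fixed as genes to report, showed no difference that passed in edgeR. DICER1 itself was at 147.7 ± 30.6 CPM in wild type, 107.4 ± 15.6 in hemizygous and 123.4 ± 7.80 in homozygous samples. Its log2 fold change was -0.46 ± 0.19 (SE; edgeR adjusted p = 1.00) in hemizygous and -0.26 ± 0.19 (edgeR adjusted p = 1.00) in homozygous samples. The log2 fold changes against wild type, hemizygous first, were 0.12 and 0.15 for DROSHA and -0.03 and 0.05 for DGCR8, which together cut primary transcripts. They were 0.00 and 0.03 for XPO5, which exports precursors, and 0.21 and 0.08 for AGO2, which carries mature microRNAs. Among pluripotency factors they were 0.28 and 0.42 for POU5F1, 0.10 and 0.13 for SOX2, 0.15 and 0.01 for NANOG and 0.22 and 0.26 for LIN28A. Leaving out 1 sample at a time moved DICER1 between -0.65 and -0.23 in hemizygous and between -0.44 and -0.02 in homozygous samples, and edgeR called none of these 9 genes in any of those fits. As lists, miRNA processing and effectors (19 genes) had medians of 0.00 and -0.01, and core pluripotency (24 genes) had medians of 0.05 and 0.02, with camera adjusted p of 0.951 and 0.682, and 0.215 and 0.123.

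Hemizygous and wild-type samples differed most at a few single genes. ASMTL, an acetylserotonin O-methyltransferase-like gene, was at 14.7 ± 3.68 CPM in hemizygous and 0.898 ± 0.148 CPM in wild-type samples, a 16.3-fold difference (log2 fold change 4.02 ± 0.30, SE). ZIC1, a zinc-finger transcription factor of the early nervous system, was at 49.9 ± 12.6 against 17.1 ± 1.14 CPM, and ZNF677, a zinc-finger gene, at 43.0 ± 6.42 against 22.4 ± 3.37 CPM. Lower in hemizygous samples were MOAP1, whose product binds the cell death protein BAX (0.113 ± 0.0251 against 1.78 ± 0.0891 CPM), and MIR4458HG, a microRNA host transcript (0.268 ± 0.158 against 3.59 ± 0.157 CPM). HTR7, a serotonin receptor gene, was at 11.4 ± 3.02 against 25.6 ± 0.0750 CPM, and ZNF492, another zinc-finger gene, at 0.344 ± 0.0300 against 1.79 ± 0.686 CPM. DESeq2 called these 7 genes, 3 higher and 4 lower, with adjusted p from 7.38e-28 for ASMTL to 0.0455 for ZNF677, and they were chosen for naming after their values were seen. The edgeR test fixed beforehand called 0 genes (141 at an unadjusted p under 0.05) and limma-voom called 0. In edgeR the lowest adjusted p was 0.0694, for ASMTL, and it was 0.0127 with the replicate number as a block, where ASMTL was the only call.

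Leaving out a sample changed which genes edgeR called. Without hemizygous 1 it called ASMTL (log2 fold change 4.27, adjusted p = 0.0120) and ITPK1, an inositol phosphate kinase gene (4.56, adjusted p = 0.00771). Without hemizygous 2 it called ASMTL (3.74, adjusted p = 0.0419) and ZNF560 (-4.67, adjusted p = 0.0142), and without wild type 1 it called EEF1B2, a translation elongation factor gene (-4.31, adjusted p = 0.0356). These 4 genes were also named after their values were seen.

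With the replicate number as a block, DESeq2 called 23 genes in hemizygous samples, 12 higher and 11 lower. Among them SKIL, a repressor of SMAD signalling, was at 337.7 ± 48.1 CPM against 209.4 ± 88.5 in wild type (adjusted p = 0.000534), and DPPA5, a pluripotency-associated gene, at 10.9 ± 6.14 against 5.64 ± 3.39 CPM (adjusted p = 0.00660). LEFTY2, a secreted inhibitor of Nodal, was at 4.56 ± 3.28 against 10.1 ± 6.31 CPM (adjusted p = 0.00388). REC8, a cohesin subunit of meiosis, was at 0.103 ± 0.0385 against 1.16 ± 0.930 CPM (adjusted p = 0.00660). MYH14, a non-muscle myosin heavy chain gene, was at 34.4 ± 3.75 against 62.5 ± 11.4 CPM (adjusted p = 2.02e-05). In edgeR, leaving out 1 sample at a time moved log2 fold changes between 0.32 and 1.21 for SKIL and 0.24 and 1.77 for DPPA5. They moved between -2.16 and -0.31 for LEFTY2, -4.14 and -2.28 for REC8, and -1.03 and -0.65 for MYH14. DESeq2 with the block was added after the data were seen, and 10.9% of its calls were false in simulated data for this comparison, against 1.01% without the block. That share came from simulated data with many changed genes and 377 calls, so it does not give the false share among these 23. In 50 simulated datasets without changed genes, this fit called a mean of 2.72 genes higher and 2.8 lower in hemizygous samples.

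**Figure D2:**
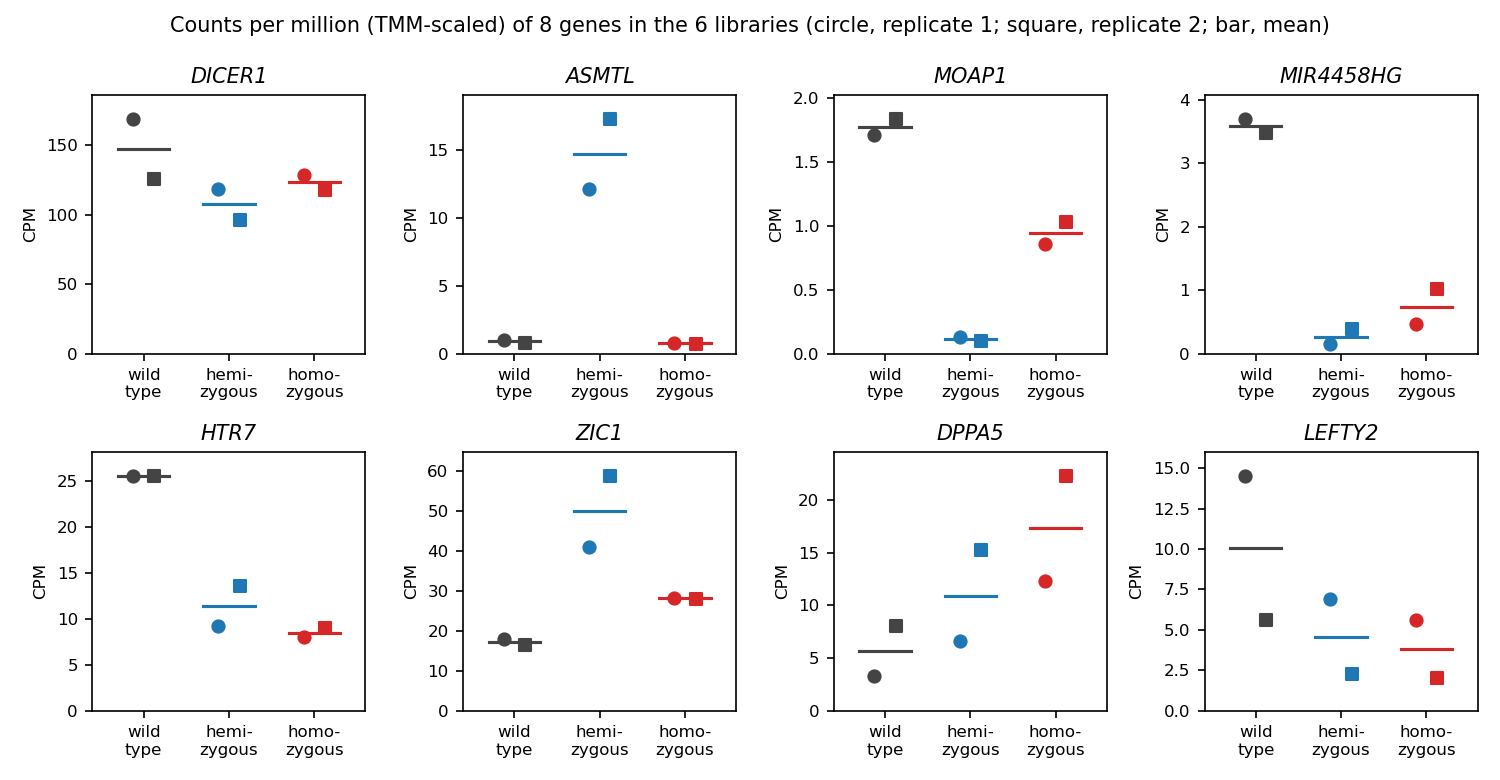
CPM of 8 genes in each sample by genotype, with circles for replicate 1, squares for replicate 2 and a bar at the mean. ASMTL is at 14.7 CPM in hemizygous samples against 0.898 in wild type, and HTR7 is lower than wild type in both edited genotypes.

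Of the 36 gene lists, 3 rose in hemizygous samples against wild type by camera, and 0 passed with an estimated correlation or with fry. Neural ectoderm markers rose (6 measured, 4 higher, median 0.09, mean 0.37, camera adjusted p = 2.21e-05, adjusted p = 0.467 with an estimated correlation), with ZIC1 as the only member past adjusted p when adjusted over the list alone. FABP7, a fatty acid binding protein of radial glia, was at 5.02 ± 1.12 against 2.99 ± 0.00329 CPM, and SOX3 and NES had log2 fold changes of -0.03 and 0.02. The neural ectoderm list passed without each sample in turn, its median being 0.02 without wild type 1 and 0.34 without wild type 2. Mesoderm markers rose (6 measured, 4 higher, median 0.33, camera adjusted p = 0.00106, adjusted p = 0.467 with an estimated correlation). Of these, PDGFRA and KDR, both growth factor receptor genes, had log2 fold changes of 0.95 and 0.45. This call was lost without wild type 1 (median 0.36, adjusted p = 0.0643) and without hemizygous 2 (0.10, adjusted p = 0.320). Neuron markers rose (11 measured, 7 higher, median 0.11, camera adjusted p = 0.00672, adjusted p = 0.474 with an estimated correlation), among them DCX, a microtubule protein of migrating neurons (5.58 ± 0.000187 against 3.29 ± 0.0159 CPM), and GAP43, a growth cone protein (41.6 ± 3.30 against 28.0 ± 5.55 CPM). The neuron call was lost without wild type 2 (0.10, adjusted p = 0.197) and without hemizygous 1 (-0.02, adjusted p = 0.309), and the median was 0.29 without wild type 1. No member of any list passed over all genes in edgeR, and over the list alone the count was 0 for the neuron and mesoderm lists.

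With the replicate number as a block, 6 lists passed camera in hemizygous samples, the same 3 and a further 3. Naive pluripotency genes were then higher (8 measured, median 0.13, camera adjusted p = 0.0177, adjusted p = 0.887 with an estimated correlation). Epithelial junction genes were lower (12 measured, median -0.08, camera adjusted p = 0.0177, adjusted p = 0.980 with an estimated correlation), and literature targets of the miR-302 family were lower (14 measured, median -0.11, camera adjusted p = 0.00327, adjusted p = 0.613 with an estimated correlation). With trends on transcript length, transcript GC and mean expression removed, the epithelial junction (cameraPR adjusted p = 0.0960) and miR-302 target calls (cameraPR adjusted p = 0.0596) were lost. The naive pluripotency call was kept (cameraPR adjusted p = 0.0425). In that blocked fit fry also passed the neural ectoderm (adjusted p = 0.0421) and neuron lists (adjusted p = 0.00113).

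A stretch of chromosome 19 was lower in hemizygous samples. From IZUMO2 to CLEC11A (GRCh38 chromosome 19, 50152548 to 50725718) 14 genes were measured, 12 had log2 fold changes below 0 and 10 below -0.5, and their median was -0.83, the lowest of 14605 runs of 14 neighbouring genes. EMC10, a subunit of a membrane protein insertase, was at 52.9 ± 9.77 against 87.0 ± 3.16 CPM and CLEC11A at 2.50 ± 1.03 against 6.06 ± 2.32 CPM. NR1H2, which encodes the liver X receptor beta, had a log2 fold change of 0.36 ± 0.18 (SE) and POLD1, the DNA polymerase delta catalytic subunit, -0.20 ± 0.16. In homozygous samples the median of the same genes was 0.12. The stretch was chosen after its values were seen.

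**Figure D3:**
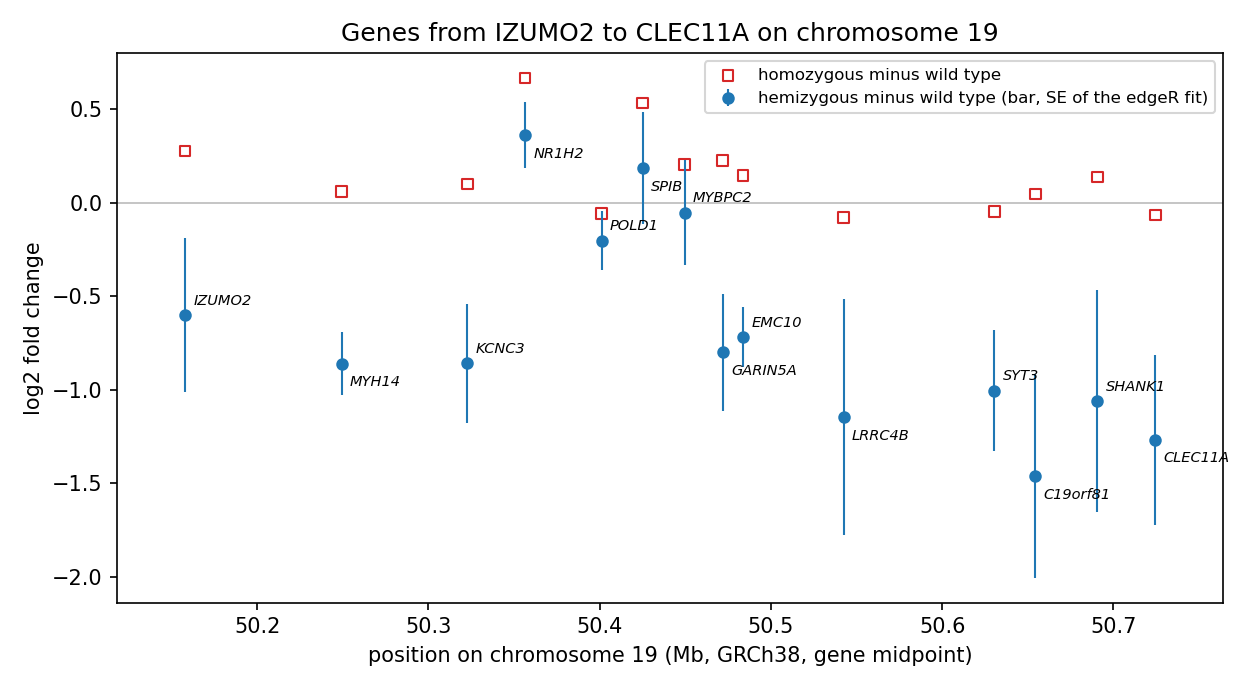
Log2 fold changes of 14 neighbouring genes along chromosome 19, hemizygous minus wild type as filled points with SE bars and homozygous minus wild type as open squares. The hemizygous median is -0.83 and the homozygous median 0.12, and NR1H2, POLD1, SPIB and MYBPC2 lie above their neighbours in hemizygous samples.

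In homozygous samples HTR7 was again lower than in wild type, at 8.50 ± 0.683 against 25.6 ± 0.0750 CPM (DESeq2 adjusted p = 3.01e-06). FGF4, a growth factor gene of pluripotent cells, was at 29.2 ± 1.36 against 17.3 ± 0.336 CPM (DESeq2 adjusted p = 0.0178), ZNF600, a zinc-finger gene, at 47.2 ± 6.97 against 25.8 ± 1.26 CPM, and CALCR, the calcitonin receptor gene, at 9.80 ± 0.350 against 4.38 ± 0.932 CPM. B3GALT5, a galactosyltransferase gene, was at 64.1 ± 1.85 against 119.3 ± 14.5 CPM and ENSG00000253507, a gene listed without a symbol, at 104.8 ± 31.5 against 218.1 ± 18.4 CPM. DESeq2 called 10 genes, 5 higher and 5 lower, these 6 among them. The other 4 were PCDHB17P, a protocadherin pseudogene, NOMO1, FBL and NDUFS1. FBL, the rRNA methyltransferase fibrillarin, was at 1.32 ± 0.0277 against 11.9 ± 12.3 CPM and NDUFS1, a subunit of respiratory complex I, at 0.823 ± 0.0505 against 6.53 ± 5.79 CPM, levels that are low for such widely expressed genes and leave in doubt how reads were assigned to them. EEF1D (9.29 ± 2.53 CPM in wild type), ALDOA of the glycolysis list (17.5 ± 1.82) and FDFT1 of the cholesterol list (2.54 ± 0.630) were likewise low for their kind. NOMO1, a gene with near-identical copies, was at 8.88 ± 5.23 against 0.783 ± 0.311 CPM, so its reads may be split between copies. DESeq2 with the replicate number as a block did not call FBL (adjusted p = 0.279) or NOMO1 (adjusted p = 0.166) and gave PCDHB17P no adjusted p. All 10 were named after their values were seen. The edgeR test called 0 genes (435 at an unadjusted p under 0.05), limma-voom 0, and edgeR with the replicate number as a block 0. Leaving out wild type 1, edgeR called EEF1B2 (log2 fold change -4.82, adjusted p = 0.0199), and leaving out hemizygous 1 it called ZNF560 (-2.33, adjusted p = 0.0338).

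With the replicate number as a block, DESeq2 called 126 genes in homozygous samples, 47 higher and 79 lower, and 9.38% of its calls were false in simulated data for this comparison. DPPA5 was at 17.3 ± 7.11 against 5.64 ± 3.39 CPM (adjusted p = 9.69e-12). LEFTY2 was at 3.82 ± 2.55 against 10.1 ± 6.31 CPM (adjusted p = 3.63e-05), and SPRY2, an inhibitor of receptor tyrosine kinase signalling, at 42.6 ± 1.41 against 74.3 ± 4.54 CPM (adjusted p = 0.000329). CYP26A1, which degrades retinoic acid, was at 1.12 ± 0.471 against 5.75 ± 5.17 CPM and PRICKLE1, a planar polarity gene, at 1.29 ± 0.113 against 6.81 ± 5.11 CPM. KDR was at 368.3 ± 11.1 against 266.3 ± 13.0 CPM (adjusted p = 0.0142) and GAP43 at 44.7 ± 2.78 against 28.0 ± 5.55 CPM (adjusted p = 0.00614).

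By camera 3 lists rose and 4 fell in homozygous samples against wild type, and 0 passed with an estimated correlation or with fry. Ribosomal protein genes rose (73 measured, 69 higher, median 0.17, camera adjusted p = 7.93e-07, adjusted p = 0.738 with an estimated correlation). The ribosomal median was 0.10 without wild type 1, and without homozygous 2 it was 0.0846 and the call was lost (adjusted p = 0.103). Hypoxia and glycolysis genes rose (18 measured, 17 higher, median 0.36, camera adjusted p = 3.95e-05, adjusted p = 0.646 with an estimated correlation). That difference came from homozygous 1, since the hypoxia median was -0.12 without it (adjusted p = 0.292) and 0.71 without homozygous 2. BNIP3, a mitophagy gene induced by low oxygen, was at 181.1 ± 107.95 CPM in homozygous and 75.5 ± 20.9 CPM in wild-type samples, while ADM, the vasodilator peptide gene also induced by low oxygen, had a log2 fold change of -1.06. Mesoderm markers rose (6 measured, 6 higher, median 0.45, camera adjusted p = 5.03e-05, adjusted p = 0.646 with an estimated correlation), 2 of them past adjusted p when adjusted over the list alone. The mesoderm list passed without each sample in turn, with KDR at 0.47 and HOXB1 at 1.29 on the log2 scale.

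Cholesterol synthesis genes fell in homozygous samples (21 measured, 2 higher, median -0.33, camera adjusted p = 0.000171, adjusted p = 0.714 with an estimated correlation). HMGCS1, an early enzyme of the pathway, had a log2 fold change of -0.64. With the replicate number as a block 10 members were lower when adjusted over the list alone, against 0 in the test without it. The cholesterol median was -0.0492 without wild type 1 (adjusted p = 0.896) and -0.22 without homozygous 2 (adjusted p = 0.104), and it was -0.57 and -0.58 without wild type 2 and without homozygous 1. Integrated stress and unfolded protein response genes fell (15 measured, 0 higher, median -0.17, camera adjusted p = 0.000476, adjusted p = 0.646 with an estimated correlation), with ASNS, asparagine synthetase, at -1.07 and CHAC1, a glutathione-degrading enzyme, at -0.65. Their median was -0.09 without wild type 1 (adjusted p = 0.290), -0.38 without wild type 2 and -0.26 without homozygous 2. Fibroblast and mesenchyme markers fell (8 measured, 1 higher, median -0.36, camera adjusted p = 0.00285, adjusted p = 0.646 with an estimated correlation), with COL1A2, a collagen chain, at 96.6 ± 3.57 against 131.4 ± 11.5 CPM. The fibroblast median was 0.05 without wild type 1 (adjusted p = 0.487), -0.65 without wild type 2 and -0.35 without homozygous 2 (adjusted p = 0.104). Chromosome 20q11.21 genes, a region often gained in cultured stem cells, fell (14 measured, 2 higher, median -0.23, camera adjusted p = 0.0167, adjusted p = 0.646 with an estimated correlation). That call was lost without wild type 1 (-0.04, adjusted p = 0.894), homozygous 1 (-0.28, adjusted p = 0.0614) or homozygous 2 (-0.21, adjusted p = 0.103), and the median was -0.37 without wild type 2. The window of 25 neighbouring genes taken for 20q11.21 (chromosome 20, 21303304 to 31952092) had a median of only -0.08. With the replicate number as a block, naive pluripotency genes were also higher (median 0.09, camera adjusted p = 0.0107, adjusted p = 0.707 with an estimated correlation) and literature targets of the miR-302 family lower (median -0.13, camera adjusted p = 0.0133, adjusted p = 0.707 with an estimated correlation). Both of these blocked calls were lost with trends on transcript length, transcript GC and mean expression removed (cameraPR adjusted p = 0.190 for each).

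**Figure D4:**
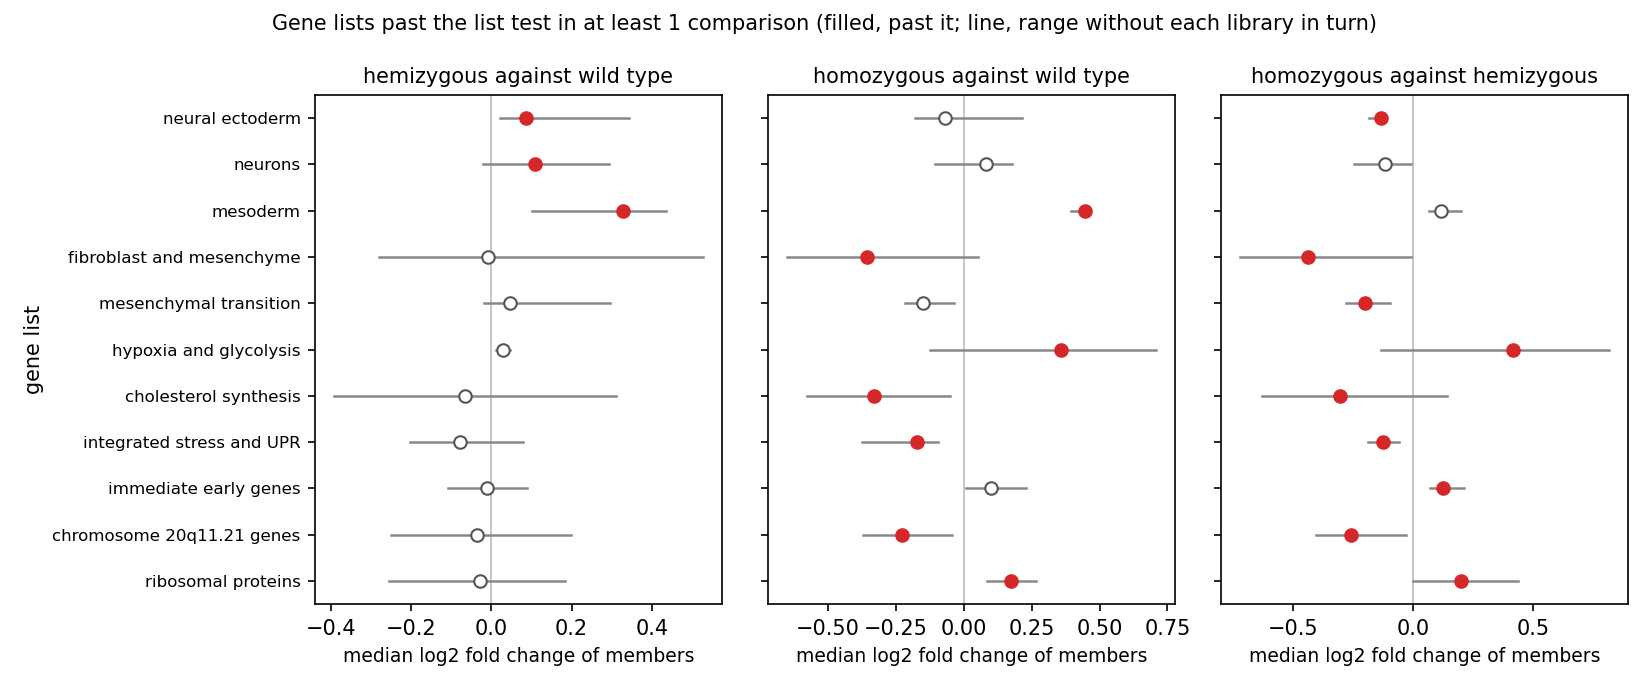
Median log2 fold change of 11 gene lists in the 3 comparisons, filled where camera with its preset correlation passed, with lines for the range over fits that leave out 1 sample. The hypoxia median for homozygous minus wild type is 0.36 and ranges from -0.12 to 0.71.

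Between homozygous and hemizygous samples ASMTL had the lowest p in edgeR, at 0.742 ± 0.0405 CPM in homozygous and 14.7 ± 3.68 CPM in hemizygous samples. In edgeR its log2 fold change was -4.30 ± 0.30 (SE), with an adjusted p of 0.0515, and with the replicate number as a block it was -4.29 with an adjusted p of 0.00940, the only call of that fit. DESeq2 called 10 genes, 8 higher and 2 lower in homozygous samples. REC8 was at 3.85 ± 1.93 against 0.103 ± 0.0385 CPM, MYH14 at 65.1 ± 2.75 against 34.4 ± 3.75 CPM, EMC10 at 96.1 ± 4.76 against 52.9 ± 9.77 CPM, and MOAP1 at 0.947 ± 0.124 against 0.113 ± 0.0251 CPM. The others were ZNF492, FAM3C2P, ENSG00000215146, ENSG00000269968 and ENSG00000273149, of which FAM3C2P was lower. With the replicate number as a block DESeq2 called 24 genes, 11 higher and 13 lower, among them UTF1, a transcription factor of undifferentiated stem cells (84.4 ± 7.85 against 43.2 ± 8.26 CPM, adjusted p = 0.000792). The edgeR test called 0 genes (124 at an unadjusted p under 0.05) and limma-voom 0. Without hemizygous 1, edgeR called ASMTL (-4.54, adjusted p = 0.00849), ITPK1 (-4.58, adjusted p = 0.00761) and ZNF560 (-2.57, adjusted p = 0.0128).

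By camera 3 lists were higher in homozygous than in hemizygous samples and 6 were lower, and with an estimated correlation these 9 had an adjusted p of 0.747 to 0.762. Ribosomal protein genes rose (median 0.20, 71 of 73 higher, camera adjusted p = 4.64e-13), and the median was 0.00 without hemizygous 1 (adjusted p = 0.930), 0.44 without hemizygous 2 and 0.10 without homozygous 2. Hypoxia and glycolysis genes rose (0.42, 16 of 18 higher, camera adjusted p = 2.96e-05), and the median was -0.13 without homozygous 1 (adjusted p = 0.185) and 0.81 without homozygous 2. Immediate early genes rose (0.12, 10 of 12 higher, camera adjusted p = 0.0133), with EGR1 at 10.1 ± 9.98 against 2.78 ± 1.46 CPM and FOS at 11.9 ± 8.80 against 5.49 ± 1.23 CPM. The immediate early call was lost without hemizygous 2 (0.20, adjusted p = 0.179), without homozygous 1 (0.07, adjusted p = 0.633) and with the replicate number as a block (adjusted p = 0.0776), and the median was 0.21 without hemizygous 1.

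Cholesterol synthesis genes fell (-0.30, 4 of 21 higher, camera adjusted p = 0.00398), with medians of 0.14 without hemizygous 1 (adjusted p = 0.0826) and -0.08 without homozygous 2 (adjusted p = 0.493), and -0.63 and -0.54 without hemizygous 2 and homozygous 1. Fibroblast and mesenchyme markers fell (-0.44, 0 of 8 higher, camera adjusted p = 0.00326), with medians of -0.01 without hemizygous 1 (adjusted p = 0.923), -0.72 without hemizygous 2 and -0.32 without homozygous 2 (adjusted p = 0.0741). Chromosome 20q11.21 genes fell (-0.26, 1 of 14 higher, camera adjusted p = 0.000837), with medians of -0.03 without hemizygous 1 (adjusted p = 0.274) and -0.40 without hemizygous 2. The window of neighbouring genes taken for 20q11.21 had a median of only -0.02 between the edited genotypes. Mesenchymal transition genes fell (-0.20, 0 of 7 higher, camera adjusted p = 0.01003), with VIM, a mesenchymal intermediate filament, at -0.33. That call was lost without hemizygous 1 (-0.10, adjusted p = 0.482), homozygous 1 (-0.24, adjusted p = 0.0614) or homozygous 2 (-0.22, adjusted p = 0.0720). Stress response genes fell (-0.12, 1 of 15 higher, camera adjusted p = 0.0170), and the call was lost without hemizygous 1 (-0.06, adjusted p = 0.482) or homozygous 1 (-0.18, adjusted p = 0.202). Neural ectoderm markers fell (-0.13, 1 of 6 higher, camera adjusted p = 0.0189), with ZIC1 the only member past adjusted p when adjusted over the list alone. The neural ectoderm call was lost without hemizygous 2 (-0.11, adjusted p = 0.332), without homozygous 1 (-0.18, adjusted p = 0.293) and with the replicate number as a block (adjusted p = 0.0720).

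The other 23 lists passed camera in none of the 3 comparisons without the block; their medians against wild type follow, hemizygous first. Among markers of other cells they were 0.10 and -0.09 for neural crest, 0.30 and 0.12 for primitive streak, -0.04 and -0.16 for definitive endoderm, and 0.00 and -0.16 for trophoblast and amnion. Among pluripotency and signalling lists they were 0.13 and 0.07 for naive pluripotency, 0.00 and -0.09 for the TGF-beta and Nodal pathway, 0.04 and 0.11 for WNT targets, and -0.08 and -0.08 for epithelial junctions. Cell cycle and death lists gave 0.00 and -0.06 for G1 to S genes, -0.04 and 0.04 for G2 and M genes, and 0.04 and 0.02 for cell cycle inhibitors. They gave 0.01 and -0.09 for p53 targets, and -0.04 and -0.15 for the BCL2 family and caspases. The interferon response gave -0.02 and -0.08, imprinted genes 0.08 and -0.12, mitochondrially encoded mRNAs 0.06 and 0.01, and replication-dependent histones -0.02 and -0.32. The miRNA host transcripts gave -0.02 and -0.13. Literature targets gave 0.01 and -0.03 for let-7, -0.11 and -0.13 for the miR-302 family, 0.04 and 0.03 for miR-17 and miR-20, 0.01 and -0.06 for miR-15 and miR-16, and 0.00 and -0.04 for miR-21. With trends on transcript length, transcript GC and mean expression removed, a correction applied after the data were seen, replication-dependent histones (5 measured) passed in homozygous against wild type (median -0.47, cameraPR adjusted p = 0.0129), a call lost with the replicate number as a block (adjusted p = 0.0538). Between the edited genotypes the corrected medians and adjusted p were then -0.21 and 0.0227 for these histones, -0.17 and 0.0346 for trophoblast and amnion, 0.06 and 0.0330 for G2 and M genes, and 0.11 and 0.0346 for miRNA processing and effectors. Median, mean and test did not share a sign in hemizygous samples for definitive endoderm, miRNA host transcripts, p53 targets, G1 to S genes, cell cycle inhibitors, the TGF-beta and Nodal pathway, chromosome 20q11.21 genes and miR-21 targets. In homozygous samples this held for neural ectoderm (median -0.07, mean 0.20, with ZIC1 and FABP7 higher when adjusted over the list alone), miRNA processing, miRNA host transcripts, cell cycle inhibitors and miR-17 targets. Between the edited genotypes it held for naive pluripotency, WNT targets and epithelial junctions.

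Both edited genotypes were compared with the same 2 wild-type samples, so calls in common were set beside simulated and independent lists. In edgeR 0 genes were shared, since it called none. By DESeq2 1 gene was shared, HTR7, lower in both, where independent lists would share 0.00123 genes. In 50 simulated pairs of unchanged groups with shared controls DESeq2 called a mean of only 0.06 and 0.1 genes lower, hemizygous first. That these pairs shared 0 was thus nearly fixed in advance, and it cannot be set beside the 1 shared gene. DESeq2 with the replicate number as a block shared 8 genes. ANKRD46, DPPA5, SKIL, TMEM161B-DT and ZIC1 were higher in both, against 0.0348 for independent lists and a simulated mean of 0.54 (highest 3). HTR7, LEFTY2 and ENSG00000253507 were lower in both, against 0.0536 and a simulated mean of 0.28 (highest 2). The simulated pairs hold no effects. With the block they had a mean of 2.52 genes called higher and 2.36 lower in homozygous samples, against 47 and 79 in the data. Their shared counts therefore do not measure what lists as long as the real ones would share. The independent lists hold no shared controls, and with 2 wild-type samples the controls could not be split. How many of the shared calls come from the shared controls is left open. Across 16199 genes, which are not independent replicates, the log2 fold changes of both comparisons had a covariance of 0.0319, against a mean of 0.0236 (0.0221 to 0.0251) in 100 simulated pairs of unchanged groups compared with shared controls. Their correlation was 0.471, against a simulated mean of 0.498 (0.472 to 0.515).

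To ask whether targets of microRNAs from the 5p and 3p arms of their hairpins moved differently, genes with a seed match in the 3' UTR were compared with the other genes among 13197 genes with an annotated 3' UTR. Of 56 seed families 0 passed cameraPR in any comparison, and 0 had an unadjusted p under 0.05. Genes with 3p sites of the miR-302 family, abundant in stem cells, differed from genes without by -0.0126 ± 0.0044 on the log2 scale in hemizygous samples (SE over 3329 genes) and by 0.0004 ± 0.0055 in homozygous samples. Genes with 3p sites of the miR-25 and miR-92 family differed by 0.0208 ± 0.0067 and 0.0355 ± 0.0079 (1740 genes), those of let-7-5p by 0.0060 ± 0.0062 and 0.0156 ± 0.0078, and those of the miR-17 and miR-20 family (5p) by 0.0082 ± 0.0046 and 0.0110 ± 0.0057. The 22 families of the 5p arm had a mean effect of 0.0022 ± 0.0075 (SD over families) in hemizygous samples and the 17 families of the 3p arm 0.0019 ± 0.0074, a difference of 0.0002 (two-sided permutation p = 0.924). In homozygous samples the means were -0.0020 ± 0.0128 and -0.0017 ± 0.0113, a difference of -0.0003 (two-sided permutation p = 0.932). For the test of single families simulated data set a limit: a shift of -0.0715 over the 2474 genes with miR-30-5p sites was not called (cameraPR adjusted p = 0.972), and a shift of -0.143 was (adjusted p = 9.03e-05). No limit was simulated for the comparison of arms.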

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

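The tests of gene length, of GC and of single libraries for the list pattern, the tests of neighbouring genes and the test of a one-copy loss on chromosome 19 were set only after the values were seen; the other tests of this part were written before their result. Both edited genotypes were compared directly, and 9 gene lists differed between them in the fit without the replicate block, where edgeR called 0 genes. The list medians, homozygous minus hemizygous on the log2 scale, were 0.20 for ribosomal proteins, 0.42 for hypoxia and glycolysis, 0.12 for immediate early genes, -0.13 for neural ectoderm, -0.44 for fibroblast and mesenchyme, -0.20 for mesenchymal transition, -0.30 for cholesterol synthesis, -0.12 for the integrated stress and unfolded protein response and -0.26 for chromosome 20q11.21 genes. Each passed camera with its preset correlation, and 0 passed with an estimated one. In the fit with the replicate number as a block 1 gene, ASMTL, differed, by -4.29 (edgeR adjusted p = 0.00940), and neural ectoderm (camera adjusted p = 0.0720) and immediate early genes (0.0776) no longer passed.

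In homozygous against wild-type samples ribosomal protein and hypoxia genes were higher and cholesterol synthesis genes lower. Length or GC bias as the whole cause is argued against for ribosomal and cholesterol genes. With trends on transcript length, GC and expression removed their medians were 0.0876 (cameraPR adjusted p = 0.00298) and -0.306 (cameraPR adjusted p = 0.000188). Both were still past this test at its preset correlation, although the ribosomal median was 0.17 before. With an estimated correlation neither list passed camera even before the correction. The hypoxia difference goes with 1 library, homozygous 1, without which the median was -0.123, and in homozygous 2 minus wild type 2 it was -0.0487. By a bound set after the values were seen, ribosomal genes met the condition against a single library as the whole cause. Their median was lowest at 0.0846, without homozygous 2, still more than 2 SE over members from 0. It was 0.149 and 0.174 in replicates 1 and 2 taken apart. That SE treats member genes as units and does not measure the spread between libraries, so this bound cannot exclude a single library. The values show only that the ribosomal median stayed above 0 without each sample in turn. Ribosomal protein genes took 5.82% of counts in homozygous 1, between the 5.19% and 6.02% of wild type 1 and 2. The ribosomal call was lost without homozygous 2. Under bounds first tried, at a median under 50% of the full one, the value of 0.0846 went with 1 library and the length and GC test decided nothing. For cholesterol genes a single library stays undecided: without wild type 1 the median was -0.0492, but it was -0.393 in replicate 1 and -0.200 in replicate 2 taken apart, so the answer turns on whether replicate numbers pair the samples. Culture state, RNA handling and genotype therefore stay open for these lists, and an effect of the genotype was not tested apart from them.

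Hemizygous samples differed widely from wild type at ASMTL, MOAP1, REC8, ZNF492, MIR4458HG and HTR7, and along 14 genes of chromosome 19. HTR7, MIR4458HG and MOAP1 were also lower than wild type in homozygous samples (8.50, 0.736 and 0.947 CPM). In hemizygous samples gain or loss of the whole region within 1 Mb is argued against for MOAP1, REC8, ZNF492, MIR4458HG and HTR7. There the median log2 fold change of neighbours lay farthest from 0 at 0.110, for ZNF492. For ASMTL gain or loss stays undecided, as only 1 neighbour was measured (-0.204). In homozygous samples neighbours were not tested. The window of 25 genes with the lowest median against wild type there, -0.286, holds HTR7 (chromosome 10, 87751512 to 93482317). A regional change around HTR7 in homozygous samples therefore stays open. ITPK1, near MOAP1, moved the other way, by 3.60, in hemizygous 2 alone (28.0 CPM, against 0.913 in hemizygous 1). ZNF849P, a pseudogene beside ZNF492, differed by -2.76, in both hemizygous samples, so a smaller change around ZNF492, or reads it shares with similar genes, stays open. On chromosome 19 loss of one of both copies of the whole stretch is argued against by 4 genes, NR1H2, POLD1, SPIB and MYBPC2, more than 3 SE above a log2 fold change of -1, and a single library by medians of -0.651 and -0.91 in hemizygous 1 minus wild type 1 and hemizygous 2 minus wild type 2. A smaller deletion, a silenced allele or domain, or another feature of the clone could each account for the stretch, and these were not tested. As the labels name no second clone per genotype, an effect of the S1344L change and a difference that arose in 1 clone cannot be separated here.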

How the results depend on the processing

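DESeq2 with the replicate block, and for seed sites limma-voom, the 2 groups alone, upper-quartile factors and the CPM filter, were chosen after the data were seen. Genes changed, 0 in edgeR in each comparison (hemizygous against wild type, homozygous against wild type, homozygous against hemizygous), were 7, 10 and 10 with DESeq2, 1, 0 and 1 with the replicate block, and 23, 126 and 24 with DESeq2 and the block. They ranged over 0 to 2, 0 to 1 and 0 to 3 without each sample in turn, and were 0 under the other alternatives; no filter removed no gene and is void. In simulated data edgeR made calls at this sample size, and DESeq2 recovered more 2-fold changes than edgeR, while about 10% of calls with the block were false. That share holds for the changed genes put into those data and was not estimated for the real calls. Shared calls, 0 in edgeR, were 1 with DESeq2, 8 with DESeq2 and the block, and 0 to 1 without each sample. Lists past camera were 3, 7 and 9, and 0 with an estimated correlation and with fry in each comparison. In hemizygous against wild type they were 6 with the replicate block and 7 with DESeq2 and the block. Without each sample they ranged over 3 to 13, 6 to 11 and 5 to 11.

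Among 1470 values for named genes 1370 kept direction and side of the threshold, 100 passed under an alternative and 0 reversed. Of 1836 list values 1694 kept both, 66 were lost, 62 passed and 14 reversed. Of 2856 seed family values 2811 kept both, 32 passed and 13 reversed. The main tests called none of these genes or seed families. No such call could be lost, and their kept values merely stayed uncalled. Apart from the fixed genes, these genes were named because DESeq2 called them, with or without the block. Their passing under those alternatives was thus set by the selection. The counts for genes and seed families therefore do not measure how stable calls are. An uncalled value that changed sign and stayed uncalled is counted as kept (31, 112 and 327 values, the largest 0.196, 0.696 and 0.0780). All list reversals came from leaving out a sample; their cause was not tested. Medians ranged, in hemizygous against wild type, over -0.39 to 0.31 for cholesterol synthesis (positive and past camera without wild type 1 or hemizygous 2), -0.70 to 0.75 for definitive endoderm (past camera at -0.57 without wild type 2), -0.16 to 0.18 for p53 targets (lower without wild type 2), -0.0803 to 0.18 for the TGF-beta and Nodal pathway (lower without wild type 2 or hemizygous 1) and -0.26 to 0.18 for ribosomal proteins (higher without hemizygous 1). In homozygous against wild type they ranged over -0.29 to 0.0735 for the TGF-beta and Nodal pathway (higher without wild type 1), -0.58 to -0.0492 for cholesterol synthesis (mean and test reversed without wild type 1) and -0.12 to 0.71 for hypoxia and glycolysis (lower without homozygous 1). Between the edited genotypes they ranged over -0.63 to 0.14 for cholesterol synthesis, -0.22 to 0.13 for mitochondrially encoded mRNAs and 0.000229 to 0.44 for ribosomal proteins (each reversed without hemizygous 1, the ribosomal list only in its mean), and -0.13 to 0.81 for hypoxia and glycolysis (lower without homozygous 1).

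Seed families past the test were 0 in each comparison and 0 without each sample, but 45 between the edited genotypes with no covariates, where site counts follow 3' UTR length. There 13 families, named by 1 member, reversed: miR-17-5p to -0.0698, miR-10-5p to -0.0444, miR-191-5p to -0.0490, miR-146-5p to -0.0649, miR-302-3p to -0.0588, miR-92-3p to -0.0632, miR-103-3p to -0.0543, miR-141-3p to -0.0777, miR-23-3p to -0.0893, miR-17-3p to -0.0429, miR-26b-3p to -0.0643, miR-155-5p to -0.0877 and miR-142-3p to -0.0657. The difference between 5p and 3p families, near 0 throughout, changed sign in hemizygous samples with 8mer sites (-0.00213), no covariates (-0.00234), limma-voom (-0.000188) and without the let-7, miR-17 and miR-302 families (-0.00117). It changed sign in homozygous samples with the shortest 3' UTR (0.00163), no covariates (0.00249) and sites of only one of miR-17 and miR-302 (0.000806). Without each sample it ranged from -0.000543 to 0.000765 and from -0.00161 to 0.000913, and no value passed; the cause was not tested. The rank of the miR-92-3p site among 7-mers ranged from 1 to 662 and from 4 to 27.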

Other observations

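The genes of the first paragraph, which DESeq2 called with the replicate number as a block, come from an alternative chosen after the data were seen, as do the ranks of 7-mers under other tests and left-out samples; the tests below were written before their results, although each pattern had been noticed in the same data. In homozygous samples MT1H, a metallothionein gene, was at 64.89 ± 2.604 against 30.7 ± 15.2 CPM (DESeq2 adjusted p = 2.48e-06) and NEFH, the heavy neurofilament chain, at 19.1 ± 1.63 against 8.81 ± 4.66 CPM (adjusted p = 0.000845). Claudin gene CLDN4 was at 18.6 ± 0.931 against 31.2 ± 9.34 CPM (adjusted p = 0.00954) and GABRP, a GABA receptor subunit found in amnion, at 6.31 ± 2.63 against 11.1 ± 4.10 CPM (adjusted p = 0.0231). In hemizygous samples RGS5, a regulator of G protein signalling, was at 62.5 ± 18.1 against 39.9 ± 7.23 CPM (adjusted p = 0.0149).

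By chromosome, the median log2 fold change of chromosome 19 genes was 0.09 in homozygous against wild type (1174 genes, cameraPR adjusted p = 3.90e-05) and 0.12 in homozygous against hemizygous samples (adjusted p = 5.26e-10). Chromosomes 16 and 4 also passed between the edited genotypes, at 0.07 and -0.08. Genes with GC-rich transcripts were higher in homozygous than in hemizygous samples, with medians of 0.11 in the fifth of genes with the highest GC and -0.10 in the fifth with the lowest. In windows of 25 neighbouring genes the medians against wild type ran from -0.18 to 0.18 in hemizygous and from -0.29 to 0.27 in homozygous samples, and the window around DICER1 was at -0.02 and -0.03.

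Sites of the miR-25 and miR-92 family (3p) were near the top of all 7-mers: GTGCAAT ranked 2 of 16263 in hemizygous and 3 in homozygous samples against wild type, and TGCAATA, the match to seed positions 2 to 7 followed by A, ranked 1 in hemizygous samples. Base composition as the whole cause is argued against, since the other 7-mers of the same bases had median ranks at 40.2% and 47.0% from the highest. A single library is argued against by the bound set in advance, the highest 5%: the worst rank was 662, or 4.07%, without wild type 1, though the rank was 62 without hemizygous 2. Both comparisons use the same wild-type samples, however, so the 2 ranks are not independent, and no simulated value of their likeness was computed; between the edited genotypes the rank was 4112. The family test did not pass (cameraPR adjusted p = 0.997 and 0.998), and the cause of the high ranks stays open.

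Lower SPRY1, SPRY2, SPRY4, DUSP6 and ETV4 in homozygous samples (median log2 fold change -0.63, and -0.40 in hemizygous samples) prompted the hypothesis of lower output of ERK signalling, of which these genes are known readouts. The 13 other measured readouts had a median of -0.0479 in homozygous samples (8 lower) and did not pass camera at 0.05. That median met the bound set in advance against the hypothesis, within 1 SE of 0. The bound was doubted only after the value was seen. Its SE of 0.150 included EGR1 at 1.76, a value that rests on homozygous 1 (10.1 ± 9.98 CPM in homozygous samples). The other 4 higher readouts lay within 1 SE of their own fit from 0, as did DUSP4, SPRED1, SPRED2, PHLDA1 and FOSL1 among the lower ones. ETV1 was at -0.20, ETV5 at -0.46 and EPHA2 at -0.37, beyond their SE. With its bound in doubt this median decides nothing, and the hypothesis stays open. In hemizygous samples the same readouts had a median of -0.09, 10 of 13 lower, and passed camera at 0.05 without adjustment, but not with an estimated correlation or with the replicate number as a block (median -0.0647).

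In hemizygous samples GCACTTA was the lowest of all 7-mers, and in homozygous samples the fifth lowest. It is the ordinary match to miR-302 positions 2 to 7 followed by A, and also the seed match of a miR-302 form that starts 1 nt earlier. Genes with GCACTTA and without the ordinary site AGCACTT differed from genes with neither by -0.0129 ± 0.010 (SE over 467 genes), which leaves the shifted form undecided. Genes with both differed by -0.0404 ± 0.0097 (782 genes), and in homozygous samples by -0.0229 ± 0.0110. Genes with AGCACTT alone differed by only -0.0048 ± 0.0046 (2547 genes), and in homozygous samples by 0.0067 ± 0.0059. AGCACTT sites without GCACTTA thus came with no lowering beyond about 1 SE. However, every AGCACTT followed by A also contains GCACTTA, so the class with both takes in these longer ordinary sites. The split therefore leaves an effect of ordinary miR-302 sites undecided, and the cause of the low rank stays open. The low rank was 255 without wild type 2 and 259 without hemizygous 1, and in homozygous samples 3130 without wild type 2 and 1793 without homozygous 1.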
